A study of Mus musculus with 8 samples.

How the data were processed

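Total RNA was profiled by RNA-seq in 8 libraries of laser-captured tissue from lumbar spinal cord of FVB/N mice at postnatal day 1: ventral horn motor neurons and surrounding white matter of WT and SMA mice, 2 libraries per group. Per the labels' protocols, frozen cross-sections were stained with Mayer's hematoxylin, regions were captured by UV laser, and RNA was purified with the RNeasy Plus Micro kit. Double-stranded cDNA was made with the NuGEN Ovation RNA-seq System, sheared and size-selected, and libraries were built with the NuGEN Encore system. Captures were therefore chosen by morphology and position, not by a marker gene. After size selection, values at microRNA and small nucleolar RNA genes can hold reads from overlapping host transcripts, which was not tested.

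The authors deposited 1 table per library with an RPKM value per gene symbol. Per the submitters' processing notes, TopHat, bedtools and DESeq were used with the mm9 mouse genome. Versions, the gene annotation, the counting rule, the use of strand and the treatment of reads with several matches are not given in the sources used here. Genes that share reads with near-identical copies (histone, hemoglobin and ribosomal protein genes, pseudogenes) and overlapping or antisense genes are therefore uncertain. Human SMN2 and the SMN transgene were not analysed here. The reference annotation at hand was of another build, and its positions were used only to pick the genes of the Dlk1-Dio3 region.

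Depth was worked out from the RPKM steps. For 17427 of the 17431 genes above 0 in at least 3 libraries (99.98%), a gene length was found at which all values were whole reads within 0.02 of a read, and 94.1% of 410 small RNA genes had the reference length. Tested on simulated data with the true depths given, the method had every read number right for 100% of 998 genes. It gave a length within 1% of the true one for 99.9%. The step that worked out the depths was not tested on simulated data. The denominators were 77.5 to 102.8 M reads per library (highest over lowest 1.33), and 1 read in a gene of 1 kb was worth 0.00972 to 0.0129 RPKM. Reads recovered on genes, a sum without genes whose reads were too many to work out, differed more. They were 65.6 and 50.8 M in WT motor neurons, 61.9 and 48.9 M in SMA motor neurons, 43.3 and 48.3 M in WT white matter and 66.8 and 62.5 M in SMA white matter, so both SMA white matter libraries lay above both WT ones. Where all libraries of a group were at 0, a floor of 3 reads per library was used, which covers counting error only.

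Tests used R 4.3.3 with limma 3.58.1 on log2(RPKM + 1), on the deposited scale. Of 23278 genes, 4154 were at 0 in all libraries and 13948 had at least 1 RPKM in at least 2 libraries. No gene symbol was repeated in the tables as read. A model of 4 group means was fitted to all 8 libraries, which share one estimate of the spread, with eBayes and trend, and two-sided p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The 6 contrasts were SMA against WT in motor neurons, in white matter and over both regions, their difference between regions (interaction), and motor neurons against white matter in WT and in SMA. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for reading, read recovery and figures.

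The model was tested on simulated data with 200 changed genes among 13948. For SMA against WT in motor neurons it recovered 9.25% of genes changed by a log2 of 1, 81.5% at 2 and 99.7% at 4; for white matter 7.76%, 75.8% and 99.7%; for the WT regions 11.3%, 80.9% and 100%. False calls made up 5.74 to 7.31% of calls, a list shifted by 0.7 was called in 5 of 5 runs, and 0 other lists were called. The simulated spread was independent between genes and equal between groups. The runs therefore tested neither lists whose genes vary together nor groups that differ in spread. In the data the estimated correlation was 0.65 in the replication-dependent histone list.

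A total of 28 gene lists were fixed before the data were examined. The cell type lists were motor neuron, spinal interneuron, oligodendrocyte precursor, myelinating oligodendrocyte, astrocyte, microglia, endothelium, pericyte, fibroblast or meninges, Schwann cell, red blood cell, and neural stem or proliferating cell. The others were ETS and pool transcription factors, complement, SMN complex and Sm core, replication-dependent histone, synaptogenesis and neuromuscular junction, synaptic vesicle and release, p53 target, unfolded protein response and amino acid stress, immediate early, cholesterol synthesis, hypoxia and glycolysis, interferon response, voltage-gated channel, transmitter receptor, nuclear-encoded respiratory chain, and ribosomal protein. Lists were tested with camera at its preset correlation of 0.01, which compares a list with all other genes, with Benjamini-Hochberg adjustment over the lists with at least 5 tested members. Lists were also tested in the interaction, over both regions and between the SMA regions, a choice made after the data were seen. Camera with an estimated correlation and fry, which tests whether a list moves one way without comparing it with other genes, were run beside it: fry called 0 lists in SMA against WT in motor neurons, in white matter and over both regions, 18 between the WT regions and 21 between the SMA regions.

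Named genes followed a rule fixed before the data were examined: per comparison and direction the 12 smallest p among genes past the threshold with no overlap between libraries, or the 5 smallest p where none passed, predicted genes without a name left out, up to 4 members of each list treated, and throughout Smn1, Agrn, Etv1, C1qa, C1qb, C1qc, Chat, Mnx1, Isl1, Mbp, Gfap and Xist. Some genes that this rule names are not reported here. For the SMA regions only counts were given. Members past the threshold over a list alone, and genes named only in the closing section, were also named after their values were seen.

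Alternatives fixed in advance were pseudocounts of 0.1 and 5 RPKM, no filter and a filter of 5 RPKM, median-of-ratios scaling, quantile normalization, eBayes without trend, array weights, the replicate number as a block, fits of the 4 compared libraries alone, camera with an estimated correlation, and leaving out each library in turn. Added after the data were seen were voom (limma) on the recovered reads and a fit without small RNA genes.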

Results

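RNA-seq was performed on 8 libraries from the lumbar spinal cord of FVB/N mice at postnatal day 1. The model was of spinal muscular atrophy (SMA), a motor neuron disease caused by loss of the survival motor neuron protein, before symptoms appear. Ventral horn motor neurons and the white matter around them were taken by laser-capture microdissection from wild-type (WT) mice and from SMA mice, which lack mouse Smn and carry the human SMN2 gene and an SMN transgene without exon 7. Each of the 4 groups (WT and SMA motor neurons, WT and SMA white matter) held 2 libraries. The deposited values were RPKM, reads per kilobase of gene model scaled to library size, for 23278 genes. Their scaling corresponded to 77.5 to 102.8 M reads per library, of which 43.3 to 66.8 M were recovered on genes. Genes with too many reads to work out, which may include the ribosomal RNA gene Rn45s, are missing from that sum. Per library, 11539 to 12796 genes reached 1 RPKM. The ribosomal RNA gene Rn45s took 19.4 to 33.4% of the RPKM sum. SMA motor neuron replicate 2 had the fewest genes at 1 RPKM and the highest Rn45s share. All levels below are mean RPKM ± SD with n = 2 libraries per group. Log2 changes are on the log2(RPKM + 1) scale with their SE, a scale that understates the change of genes with low levels.

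The regions separated along the first principal component, which held 68.6% of the variance. The second component held 11.3% and had the SMA motor neuron libraries at its ends, at 48.5 for replicate 1 and -55.7 for replicate 2. Across genes, which are not independent replicates, the correlation between replicates was 0.889 in SMA motor neurons, 0.963 in WT motor neurons, 0.936 in WT white matter and 0.941 in SMA white matter. Xist, transcribed from the inactive X chromosome of females, lay between 12.6 and 37.0 RPKM in replicate 1 of each group and at 0.0581 RPKM or less in replicate 2 of each group. Each group thus held 1 library with and 1 without Xist. Ddx3y, on the Y chromosome, went the other way, listed at 0 in replicate 1 and at 0.628 RPKM or more in replicate 2 of each group. These values argue against replicates that were technical repeats of the same animals. The labels name no animals, neither for replicates nor for the 2 regions, so p-values measure only the spread between these libraries. Regions of the same animals could not be paired.

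Smn1, the targeted gene, was at 6.82 and 2.93 RPKM in the WT motor neuron libraries (762 and 279 reads) and at 5.30 and 14.3 RPKM in the WT white matter libraries (565 and 1700 reads). It was listed at 0 in all 4 SMA libraries. A floor of 3 reads per library, which covers counting error only, was set against the WT mean. By this measure Smn1 was at least 164-fold lower in SMA motor neurons and at least 400-fold lower in SMA white matter. Set against the lower WT library of each region, these bounds would be smaller. A listed 0 need not mean absence, since Hmgcs1, an enzyme gene of cholesterol synthesis, was listed at 0 in all 8 libraries. With WT replicates that differed by more than 2-fold in either region, Smn1 did not pass limma with Benjamini-Hochberg adjustment (adjusted p = 0.556 in motor neurons and 0.290 in white matter).

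The comparison of WT motor neurons with WT white matter shows what each capture held. Motor neuron captures had more Chat, the acetylcholine-synthesizing enzyme (19.4 ± 7.96 against 0.120 ± 0.0858 RPKM), Isl1 (31.6 ± 4.74 against 0.265 ± 0.282 RPKM) and Mnx1 (6.43 ± 1.18 against 0.0356 ± 0.0503 RPKM). Isl1 and Mnx1 are transcription factors of motor neuron identity. White matter captures had more Mbp (1400 ± 792 against 25.4 ± 11.9 RPKM), which encodes a protein of compact myelin, and more of the astrocyte filament gene Gfap (167 ± 28.5 against 6.92 ± 2.998 RPKM). These 5 passed limma (adjusted p of 2.9e-04 or less). The complement genes C1qa, C1qb and C1qc were lower in motor neurons by 2.87 ± 0.43, 3.16 ± 0.36 and 2.63 ± 0.26 on the log2 scale (limma adjusted p = 0.00107, 2.4e-04 and 1.4e-04). Agrn, which encodes the synapse organizer agrin, was at 38.0 ± 0.986 RPKM in motor neurons and 31.6 ± 4.31 in white matter, and Etv1, an ETS transcription factor, at 7.54 ± 0.415 and 3.59 ± 1.06. Neither Agrn (limma adjusted p = 0.441), Etv1 (0.0785), Smn1 (0.240) nor Xist (0.858) passed between the WT regions. Etv1 passed under 4 of 21 alternatives (limma adjusted p = 0.0301 to 0.326 over the 21).

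In all, 3967 of 13948 genes differed between the WT regions (limma, adjusted p under 0.05), with 2593 higher and 1374 lower in motor neurons. The 12 with the smallest p on the motor neuron side were Ngfr, Ret, Nefm, Fxyd7, Atp1b1, Snap25, Sncg, Disp2, Kcnk9, Arhgap36, Slitrk1 and Tubb3, with log2 differences of 4.31 to 6.84 (limma adjusted p = 9.0e-06 for each). Among them the neurofilament gene Nefm reached 1602 ± 271 RPKM against 13.2 ± 4.18 in white matter, the neurotrophic factor receptor Ret 149 ± 6.43 against 2.64 ± 0.705, and the sodium pump subunit Atp1b1 523 ± 24.6 against 14.9 ± 2.28. On the white matter side the smallest p included those of Enpp6, S100a6, Cnp, Gfap, Bcas1, Tns3, Gpr17, Pllp, Ugt8a, Mir1897 and Cldn11 (limma adjusted p of 4.9e-05 or less). Enpp6, a marker of newly formed oligodendrocytes, was at 52.0 ± 14.4 RPKM in white matter and 0.777 ± 0.0443 in motor neurons, and the myelin tight junction gene Cldn11 at 95.3 ± 40.5 and 0.688 ± 0.769. The share of these calls higher in motor neurons was 65.4% on the deposited scale, 55.6% with median-of-ratios scaling and 51.7% after quantile normalization. Leaving out a compared library lowered the count to 2015 (without WT motor neuron replicate 1), 2108 (motor neuron replicate 2), 2586 (white matter replicate 1) or 2118 (white matter replicate 2).

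Of the 28 gene lists, 8 were higher and 11 lower in WT motor neurons than in WT white matter by camera with its preset correlation. On the higher side, 23 of 26 motor neuron genes were higher one by one (23 adjusted over the list alone; camera adjusted p = 1.7e-16). So were 35 of 39 synaptic vesicle genes (35 adjusted over the list alone; camera adjusted p = 5.2e-18) and 36 of 44 voltage-gated channel genes (38; 1.5e-15). Among 41 transmitter receptor genes 24 were higher (27 adjusted over the list alone; camera adjusted p = 9.1e-09), and 36 of 73 nuclear-encoded respiratory chain genes were (43; 3.0e-09). Synaptogenesis and neuromuscular junction genes had 21 higher and 5 lower of 46 (24 and 6 adjusted over the list alone; camera adjusted p = 2.9e-04). Hypoxia and glycolysis genes had 13 and 3 of 28 (14 and 3; 0.00294) and spinal interneuron genes 8 and 1 of 15 (10 and 1; 0.00671). With an estimated correlation none of these 8 held: adjusted p = 0.153 to 0.381 with an estimated correlation. Examples are Nefl (1303 ± 303 against 51.2 ± 2.26 RPKM), the vesicle protein Syp (221 ± 50.0 against 9.18 ± 3.97 RPKM), the sodium channel Scn2a1 (57.1 ± 4.49 against 3.52 ± 1.36 RPKM), the NMDA receptor subunit Grin1 (143 ± 24.4 against 3.99 ± 1.22 RPKM) and the interneuron peptide Sst (141 ± 20.8 against 7.15 ± 4.99 RPKM).

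On the lower side, 21 of 24 microglia genes were lower in motor neurons (22 adjusted over the list alone; camera adjusted p = 1.2e-14). This was the list whose call held with an estimated correlation (adjusted p = 0.0433 with an estimated correlation). Myelinating oligodendrocyte genes had 22 lower and 1 higher of 26 (24 and 1 adjusted over the list alone; camera adjusted p = 7.0e-17) and oligodendrocyte precursor genes 15 lower of 18 (16, with 1 higher; 4.2e-10). Astrocyte genes had 14 lower and 1 higher of 24 (16 and 1 adjusted over the list alone; camera adjusted p = 1.3e-06) and neural stem or proliferating cell genes 21 lower of 34 (27; 1.4e-11). Replication-dependent histone genes, transcribed in dividing cells, had 36 lower of 53 (38 adjusted over the list alone; camera adjusted p = 5.4e-16) and ribosomal protein genes 25 lower of 75 (31; 7.4e-13). Fibroblast or meninges genes had 10 lower and 2 higher of 16 (10 and 2 adjusted over the list alone; camera adjusted p = 5.7e-05) and complement genes 8 and 4 of 19 (8 and 4; 0.0136). Interferon response genes had 5 and 1 of 19 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0136) and red blood cell genes 3 and 1 of 12 (3 and 1; 0.0216). Apart from microglia, these lower lists had adjusted p = 0.153 to 0.346 with an estimated correlation. The red blood cell call was lost without WT motor neuron replicate 1 (camera adjusted p = 0.0683) or WT white matter replicate 1 (0.0818), and the interferon call without WT motor neuron replicate 1 (0.0683) or after quantile normalization (0.0556). Not called were the ETS and pool transcription factors, endothelium, pericyte, Schwann cell, SMN complex and Sm core, p53 target, unfolded protein response, immediate early and cholesterol synthesis lists (camera adjusted p = 0.0818 to 0.965). In the ETS list (median log2 0.19) and the SMN complex list (0.015) the camera direction was down although median and mean lay above 0, and in the unfolded protein response list the median (-0.14) and the mean (0.021) differed in sign.

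Between the SMA regions, 4295 genes differed (limma, adjusted p under 0.05), with 1897 higher and 2398 lower in motor neurons. A total of 2864 genes were called in the same direction in both genotypes, 1679 higher and 1185 lower in motor neurons, where independent lists of these sizes would share 353 and 236, and 1 gene was called in opposite directions. The share higher in SMA motor neurons was 44.2% on the deposited scale, 53.8% with median-of-ratios scaling and 51.7% after quantile normalization. Camera called 20 of the 28 lists in SMA, 8 higher and 12 lower in motor neurons, none of which held with an estimated correlation (smallest adjusted p = 0.0730 with an estimated correlation). The count fell to 2272 without SMA white matter replicate 1, to 2410 without SMA white matter replicate 2 and to 2415 in a fit of the 4 compared libraries alone.

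The main question of the series was how presymptomatic SMA motor neurons differ from WT motor neurons. The p53 target genes rose as a group in SMA motor neurons: 23 of 27 had a positive log2 change, with a median of 0.59, and the list passed camera (adjusted p = 2.9e-10; adjusted p = 0.204 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, was at 59.2 ± 1.12 RPKM in WT and 257 ± 16.9 RPKM in SMA motor neurons, a log2 change of 2.10 ± 0.27 (limma adjusted p = 0.258). It was the 1 member past the threshold adjusted over the list alone, against 0 over all genes. Plk2, a polo-like kinase, was at 6.23 ± 0.210 and 16.3 ± 5.71 RPKM, Gtse1, which binds p53, at 0.977 ± 0.02002 and 3.63 ± 1.62, and Sesn2, a stress-induced sestrin, at 7.26 ± 2.17 and 15.6 ± 1.96. Against the WT mean, the median p53 target gene lay 0.73 higher in SMA replicate 1 and 0.33 higher in replicate 2. The camera call held without any single one of the 8 libraries.

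The complement and microglia lists also passed camera upward in SMA motor neurons, by small medians. The complement list holds C1qa, C1qb and C1qc, and it was not tested without them. The median was 0.18 for complement with 12 of 19 positive (camera adjusted p = 0.0149) and 0.17 for microglia with 16 of 24 positive (0.00204), both with adjusted p = 0.289 with an estimated correlation. The subunits of C1q, which starts the classical complement pathway, were at 1.65 ± 1.67 and 5.55 ± 0.408 RPKM (C1qa), 5.38 ± 3.19 and 22.7 ± 5.45 RPKM (C1qb) and 9.21 ± 1.49 and 27.8 ± 6.50 RPKM (C1qc) in WT and SMA motor neurons. Their log2 changes were 1.47 ± 0.43, 1.97 ± 0.36 and 1.48 ± 0.26 (limma adjusted p = 0.752, 0.556 and 0.556). Adjusted over the list alone these 3 complement genes passed, against 0 over all genes, but C1q, Etv1 and Agrn were chosen with knowledge of published work on these samples, so this is not independent evidence. In the microglia list, Cd68, a lysosomal membrane protein, was at 0.415 ± 0.264 and 3.63 ± 0.731 RPKM and Tyrobp, a signalling adaptor, at 7.06 ± 0.400 and 15.9 ± 2.32 RPKM, and both passed adjusted over the list alone. In WT, C1q and microglia genes were lower in motor neuron than in white matter captures. The complement call was lost without SMA replicate 1 (camera adjusted p = 0.0803) or 2 (0.211), and the microglia call without WT replicate 1 (0.0501) or SMA replicate 2 (0.347). Against all genes the microglia median was 0.22, and it was -0.016 without SMA replicate 2, 0.33 without SMA replicate 1 and 0.34 without WT replicate 2. The complement median of 0.23 became 0.12 and 0.36 without WT replicates 1 and 2 and 0.14 and 0.11 without SMA replicates 1 and 2.

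Lists of other cell types shifted in the same captures. Spinal interneuron genes rose (14 of 15 positive, median 0.43; camera adjusted p = 0.00164; adjusted p = 0.489 with an estimated correlation). The transcription factor Lhx5 was at 0.534 ± 0.0115 and 2.58 ± 0.0411 RPKM and the inhibitory vesicle transporter Slc32a1 at 7.30 ± 5.18 and 16.3 ± 1.36 RPKM. Astrocyte genes (15 of 24 positive, median 0.097; camera adjusted p = 0.0221) and fibroblast or meninges genes (13 of 16 positive, median 0.27; 0.0149) rose too, each with adjusted p = 0.859 with an estimated correlation. Gfap was at 6.92 ± 2.998 and 20.9 ± 3.74 RPKM, the 1 astrocyte gene past the threshold adjusted over the list alone, and the collagen gene Col1a1 at 0.236 ± 0.295 and 2.42 ± 1.25 RPKM. Motor neuron genes fell as a group (22 of 26 negative, median -0.38; camera adjusted p = 0.0207; adjusted p = 0.859 with an estimated correlation). Among them Chodl, a marker of fast motor neurons, was at 79.2 ± 2.70 and 31.8 ± 1.34 RPKM, and the axon guidance gene Slit2 at 43.6 ± 1.25 and 24.9 ± 18.3 RPKM. The interneuron call was lost without SMA replicate 2 (camera adjusted p = 0.252). The motor neuron call was lost without WT replicate 1 (0.0560), WT replicate 2 (0.0744) or SMA replicate 1 (0.747), or with a pseudocount of 0.1 RPKM (0.120). The astrocyte call was lost without WT replicate 2 (camera adjusted p = 0.211), SMA replicate 1 (0.149) or SMA replicate 2 (0.201). The meninges call was lost without WT replicate 1 (0.0501), SMA replicate 1 (0.136) or SMA replicate 2 (0.0540).

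**Figure D1:**
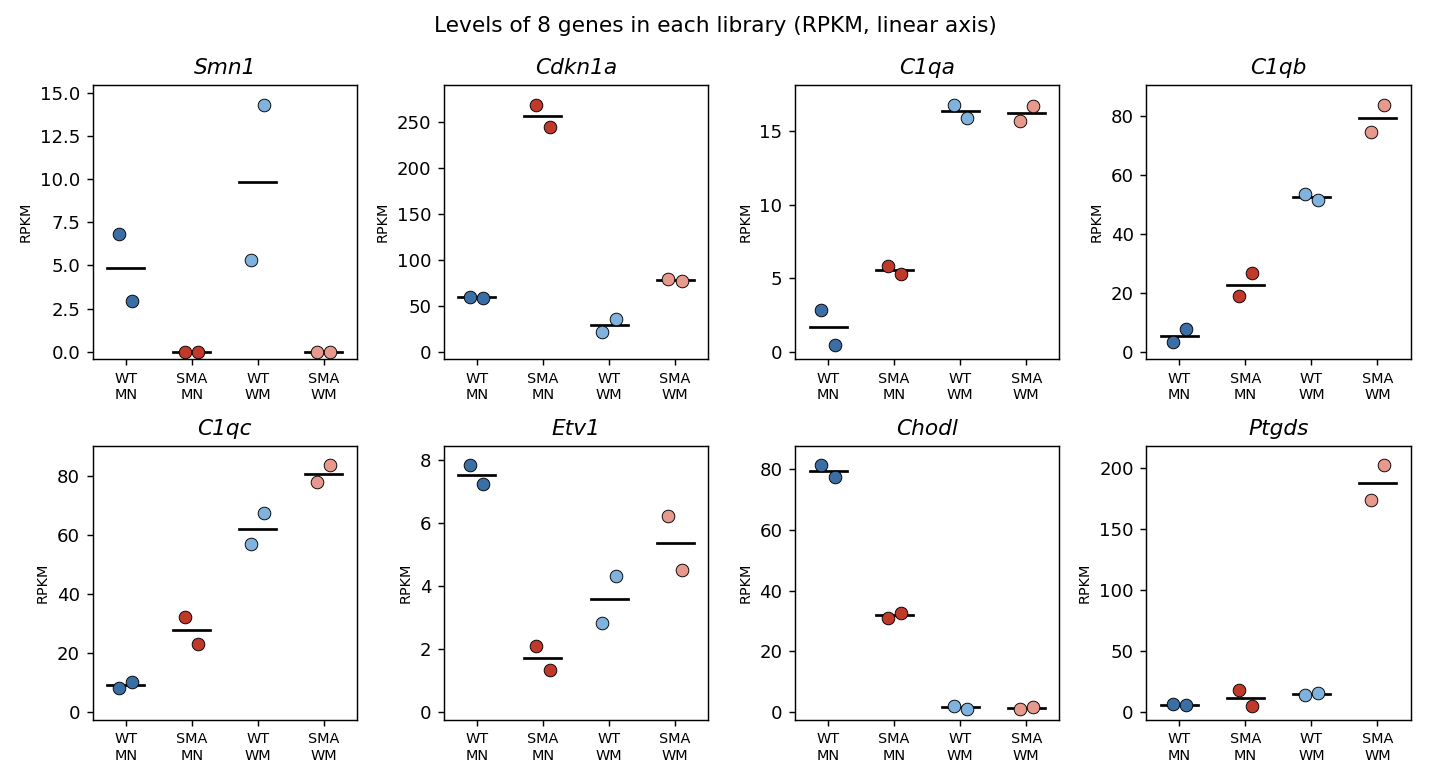
Levels of 8 genes (RPKM, linear axis, 1 panel per gene) in each library; circles are single libraries, placed side by side as replicates 1 and 2, and black lines are group means for WT and SMA motor neuron (MN) and white matter (WM) captures. Smn1 is listed at 0 in the 4 SMA libraries, and Cdkn1a has a mean of 257 RPKM in SMA MN against 59.2 in WT MN.

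Gene by gene, no change between SMA and WT motor neurons passed limma (0 of 13948 genes, smallest adjusted p = 0.258; 609 genes at unadjusted p under 0.05 and 0 genes by voom on recovered reads). Of the 609, 280 were higher and 329 lower, where 697 would come by chance. The smallest p among higher genes, after Cdkn1a, C1qc and C1qb, belonged to C1qtnf2, a C1q-related secreted protein (0.0544 ± 0.0770 and 2.33 ± 0.0215 RPKM), and Cd68. Among lower genes they belonged to the olfactory receptor pseudogene Olfr329-ps (2.80 and 2.72 RPKM in WT, listed at 0 in both SMA libraries). They were followed by the microRNA gene Mir379 (17.0 ± 8.03 and 1.94 ± 1.71 RPKM), the ATP-gated channel gene P2rx7 (4.11 ± 1.65 and 0.400 ± 0.0131 RPKM) and, after Smn1, the small nucleolar RNA gene Snord42a (24.1 ± 15.0 and 3.93 ± 1.36 RPKM). Each had limma adjusted p = 0.556. Etv1 was at 7.54 ± 0.415 RPKM in WT and 1.72 ± 0.522 RPKM in SMA motor neurons (log2 change -1.66 ± 0.35; limma adjusted p = 0.556), and it passed adjusted over the list of 15 ETS and pool factors alone. Agrn was at 38.0 ± 0.986 and 31.2 ± 0.0469 RPKM, Chat at 19.4 ± 7.96 and 13.2 ± 2.02, Isl1 at 31.6 ± 4.74 and 22.8 ± 1.65, and Mnx1 at 6.43 ± 1.18 and 6.36 ± 0.814. Mbp was at 25.4 ± 11.9 and 52.9 ± 19.4 RPKM and Xist at 6.29 ± 8.86 and 8.93 ± 12.6. Leaving out SMA replicate 1 gave 123 genes (16 higher and 107 lower), with the remaining SMA library assumed to vary like the other groups. Leaving out any of the other 7 libraries gave 0.

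The other 21 lists did not pass in motor neurons (camera adjusted p = 0.0563 to 0.971). Synaptogenesis and neuromuscular junction genes, a list with Agrn, had 22 of 46 positive (median -0.072; camera adjusted p = 0.971) and SMN complex and Sm core genes 11 of 29 (-0.17; 0.664). Myelinating oligodendrocyte genes had 18 of 26 positive (0.17; 0.0824) and pericyte genes 11 of 13 (0.39; 0.0563). Voltage-gated channel genes had 13 of 44 positive (median -0.19; camera adjusted p = 0.0824), unfolded protein response genes 12 of 24 (-0.039; 0.725) and immediate early genes 7 of 18 (-0.077; 0.305). Adjusted over their lists alone, Sdf2l1, an endoplasmic reticulum chaperone component (log2 change -2.05 ± 0.42), and Fos (1.83 ± 0.39) passed, with limma adjusted p = 0.556 over all genes. Median, mean and test differed in sign for the immediate early, histone, interferon response and ribosomal protein lists.

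**Figure D2:**
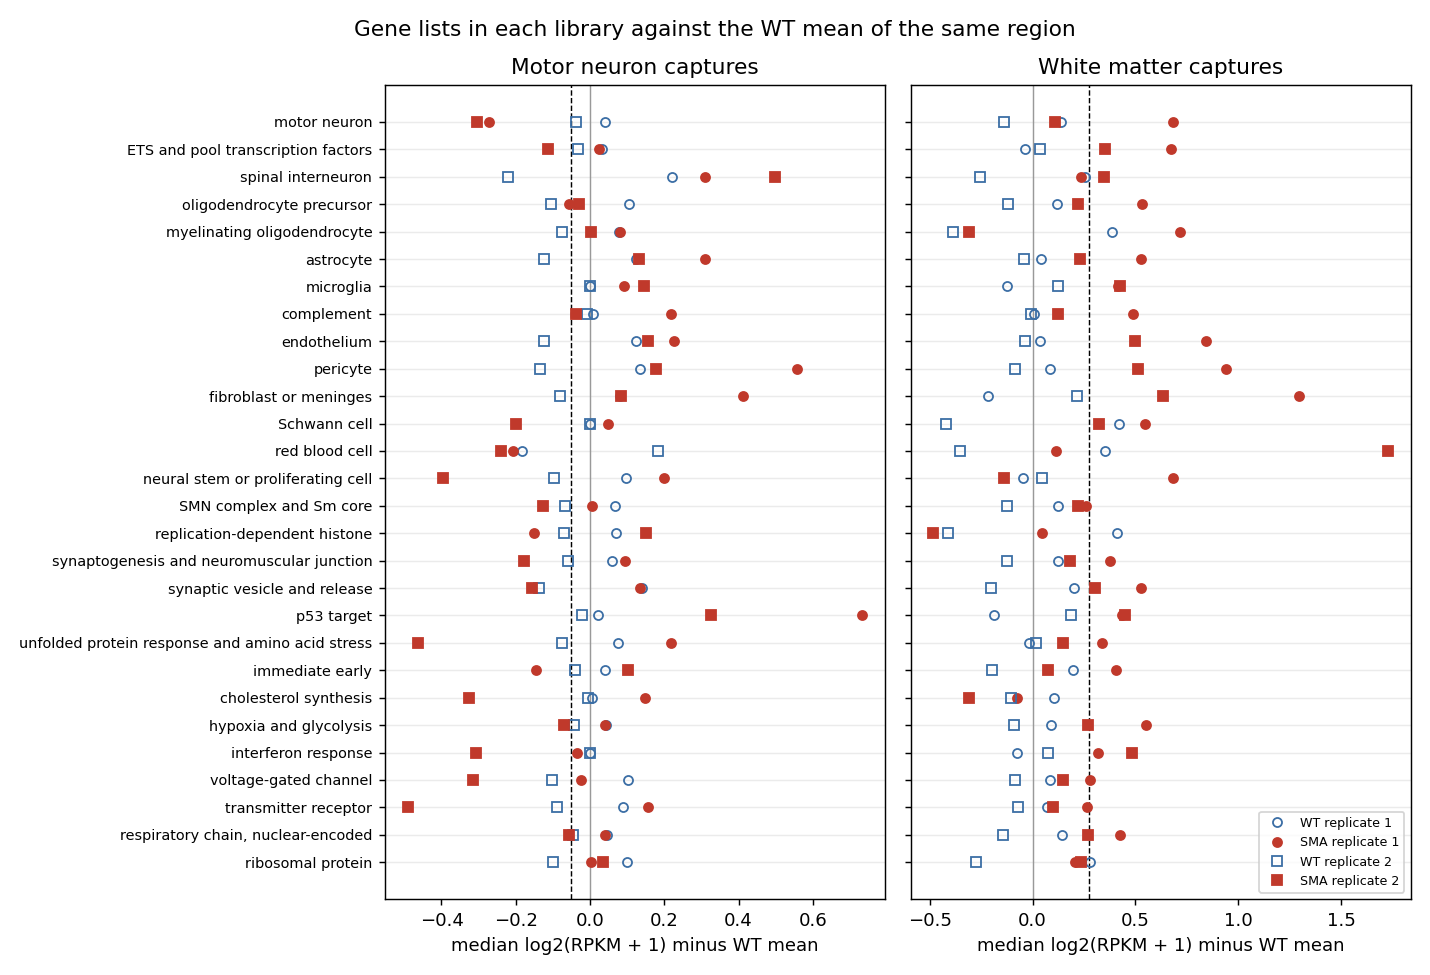
For each of the 28 gene lists, the median over its genes of log2(RPKM + 1) minus the WT mean of the same region, in motor neuron captures (left) and white matter captures (right). Open symbols are WT and filled symbols SMA libraries, circles replicate 1 and squares replicate 2. The grey line marks 0 and the dashed line the median change of all genes in SMA. The p53 target list lies at 0.73 and 0.33 in the SMA motor neuron libraries, and the fibroblast or meninges list at 1.30 and 0.63 in the SMA white matter libraries.

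The same question was asked of the white matter. There the median change over all genes was 0.27 on the deposited scale, 0.0015 with median-of-ratios scaling and -0.0060 after quantile normalization, so the list results below are also set against other genes. Several lists of non-neural cells rose as groups in SMA white matter. They were fibroblast or meninges genes (16 of 16 positive, median 0.99; camera adjusted p = 2.3e-05), endothelium genes (22 of 22, 0.74; 1.3e-04) and pericyte genes (12 of 13, 0.82; 0.0105). Each had adjusted p = 0.785 with an estimated correlation. A total of 4 meninges genes passed adjusted over the list alone, against 0 over all genes. They were the collagens Col1a1 (17.7 ± 1.80 and 46.8 ± 18.1 RPKM in WT and SMA) and Col3a1 (7.98 ± 3.14 and 23.7 ± 9.63 RPKM), the growth factor Igf2 (51.4 ± 9.75 and 144 ± 11.2 RPKM) and the transporter Slc6a13 (2.01 ± 0.508 and 5.93 ± 0.684 RPKM). Among endothelium and pericyte genes, the glucose transporter Slc2a1 was at 27.6 ± 1.10 and 46.9 ± 4.35 RPKM, the junction protein Cdh5 at 2.80 ± 0.529 and 6.53 ± 1.80, and Higd1b at 0.734 ± 0.381 and 3.59 ± 1.44. The meninges and endothelium calls held without any single library, but their medians against all genes fell from 0.71 and 0.47 to 0.41 and 0.28 without SMA white matter replicate 1. By contrast, the pericyte call was lost without WT white matter replicate 1 (camera adjusted p = 0.0938) or SMA white matter replicate 1 (0.158).

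Replication-dependent histone genes fell as a group in SMA white matter (43 of 53 negative, median -0.19; camera adjusted p = 3.8e-14), as did cholesterol synthesis genes (16 of 22 negative, median -0.22; 8.1e-07). Both had adjusted p = 0.785 with an estimated correlation. Hist2h2ac was at 37.7 ± 8.83 and 21.4 ± 1.36 RPKM and Hist1h3g at 29.9 ± 10.1 and 17.3 ± 6.54, while the squalene epoxidase gene Sqle was at 65.4 ± 7.66 and 46.5 ± 7.54 RPKM and Nsdhl at 39.2 ± 1.44 and 29.9 ± 0.106. The WT white matter libraries themselves lay at 0.41 and -0.41 around their mean for the histone list, whose call was lost without WT replicate 1 (camera adjusted p = 0.379). Astrocyte genes (23 of 24 positive, median 0.40; camera adjusted p = 0.0242; adjusted p = 0.785 with an estimated correlation) and synaptic vesicle genes (36 of 39, 0.44; 0.0157; adjusted p = 0.892 with an estimated correlation) rose on the deposited scale. The glutamine synthetase gene Glul was at 45.9 ± 4.91 and 93.5 ± 4.80 RPKM and the complexin gene Cplx2 at 5.61 ± 0.823 and 13.4 ± 3.26 RPKM. Glul passed adjusted over the astrocyte list alone. Nuclear-encoded respiratory chain genes rose on that scale too (68 of 73 positive, median 0.33; camera adjusted p = 0.00888; adjusted p = 0.785 with an estimated correlation). Against all genes their median was 0.060, and after quantile normalization it was -0.028 with the direction turned. With median-of-ratios scaling the astrocyte, synaptic vesicle and respiratory chain calls ended (camera adjusted p = 0.253, 0.0756 and 0.962), as they did after quantile normalization (0.351, 0.0618 and 0.626). Voom on recovered reads ended the respiratory chain call too. All 3 calls were also lost without WT white matter replicate 2 (0.0600, 0.793 and 0.793) or SMA white matter replicate 1 (0.492, 0.227 and 0.155), and the astrocyte call without WT white matter replicate 1 (0.0788).

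Gene by gene, none of 13948 genes passed limma in white matter (0 genes, smallest adjusted p = 0.173; 880 at unadjusted p under 0.05, 844 higher and 36 lower), while voom on recovered reads called 1, Ptgds. With median-of-ratios scaling the genes at unadjusted p under 0.05 were 218 higher and 137 lower, and after quantile normalization 256 and 192. Ptgds, the lipocalin-type prostaglandin D synthase, was at 15.0 ± 1.16 RPKM in WT and 188 ± 19.96 RPKM in SMA white matter, a log2 change of 3.56 ± 0.43 (limma adjusted p = 0.173; 0.0384 by voom, within 2.3e-04 to 0.964 over the alternatives). The next higher genes were Mir453 (0.203 ± 0.109 and 5.09 ± 0.824 RPKM), the tropomyosin gene Tpm1 (38.5 ± 2.41 and 90.4 ± 0.0814), Cdkn1a (28.5 ± 10.6 and 78.0 ± 1.15) and the retinoic acid binding protein gene Crabp1 (11.8 ± 0.0424 and 29.5 ± 3.76), with limma adjusted p of 0.195 to 0.634. On the lower side, after Smn1, were the small RNA genes Mir339 (13.3 ± 12.2 and 0.361 ± 0.206 RPKM), Snord83b (3.81 ± 2.01 and 0.189 ± 0.268), Mir346 (listed at 0 in both SMA libraries) and Mir377 (14.8 ± 10.9 and 1.29 ± 1.82), each with limma adjusted p = 0.727. The C1q genes were at 16.3 ± 0.650 and 16.2 ± 0.722 (C1qa), 52.4 ± 1.36 and 79.1 ± 6.51 (C1qb) and 62.3 ± 7.54 and 80.9 ± 4.02 RPKM (C1qc), Etv1 at 3.59 ± 1.06 and 5.37 ± 1.21, and Agrn at 31.6 ± 4.31 and 35.7 ± 3.97. Mbp was at 1400 ± 792 and 1864 ± 908 RPKM, Gfap at 167 ± 28.5 and 209 ± 41.6, and Xist at 15.6 ± 22.0 and 18.5 ± 26.2, while Chat, Isl1 and Mnx1 stayed at means of 0.454 RPKM or less.

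The 20 lists not called in white matter had camera adjusted p = 0.152 to 0.952. The p53 target list had 25 of 27 positive (median 0.40; camera adjusted p = 0.157), with Cdkn1a past the threshold adjusted over the list alone. Microglia genes had 22 of 24 positive (0.38; 0.306), red blood cell genes 12 of 12 (0.76; 0.157) and Schwann cell genes 5 of 7 (0.25; 0.469). Median and mean lay above 0 and the camera direction was down for the interneuron, myelinating oligodendrocyte, proliferating cell, SMN complex, unfolded protein response, channel, receptor and ribosomal protein lists.

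Whether SMA changed the regions differently was tested as an interaction, and no gene passed limma (0 of 13948, smallest adjusted p = 0.107; 693 at unadjusted p under 0.05, 85 positive and 608 negative; 0 by voom). The most negative by p was Mir453, at 22.0 ± 1.99 RPKM in WT and 7.06 ± 0.693 in SMA motor neurons against 0.203 ± 0.109 and 5.09 ± 0.824 in white matter (interaction -3.85 ± 0.44; limma adjusted p = 0.107). It was followed by Tpm1, the nucleotide-cleaning enzyme gene Nudt1, the growth factor gene Igf1 and the nuclear receptor gene Ppard. On the positive side stood Snord83b, the galanin gene Gal, Mir100, Etnk2 and Snora3, and these 9 had limma adjusted p = 0.883. Igf1 was at 55.3 ± 2.08 and 27.2 ± 1.86 RPKM in WT and SMA motor neurons and at 3.76 ± 0.816 and 9.08 ± 2.29 in white matter, and Gal at 2.66 ± 0.0581 and 11.2 ± 2.25 against 1.45 ± 1.18 and 0.140 ± 0.176. Among the genes followed throughout, the interaction ranged from -2.14 ± 0.49 for Etv1 to 1.48 ± 0.60 for C1qa (both limma adjusted p = 0.883). The median interaction over all genes was -0.33 on the deposited scale, -0.030 with median-of-ratios scaling and -0.0096 after quantile normalization. The genes at unadjusted p under 0.05 were 190 positive and 221 negative with median-of-ratios scaling, and 224 and 205 after quantile normalization. Leaving out SMA motor neuron replicate 1 gave 17 genes, 1 positive and 16 negative.

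Over both regions together, 4 SMA against 4 WT libraries with region held in the model, no gene passed limma (0 of 13948, smallest adjusted p = 0.0534; 836 at unadjusted p under 0.05, 703 higher and 133 lower). By voom on recovered reads 1 passed, Cdkn1a. With median-of-ratios scaling the genes at unadjusted p under 0.05 were 352 higher and 282 lower, and after quantile normalization 374 and 268. The 4 libraries per genotype were treated as independent. The 2 regions may come from the same animals, and p-values over both regions would then be too small. Cdkn1a had a mean log2 change of 1.78 ± 0.19 (limma adjusted p = 0.0534; 0.0225 by voom, within 0.0194 to 0.574 over the alternatives). Next were Ptgds, the metallothionein genes Mt2 and Mt1, and Crabp1. Mt2 was at 85.4 ± 27.1 and 182 ± 79.9 RPKM in WT and SMA motor neurons and at 279 ± 88.7 and 943 ± 28.4 in white matter, and Mt1 at 48.1 ± 17.5 and 108 ± 3.83 and at 238 ± 32.8 and 433 ± 30.2 (limma adjusted p = 0.520 and 0.544). On the lower side were Smn1 (-2.88 ± 0.34; limma adjusted p = 0.0747, within 0.0272 to 0.584 over the alternatives and under 0.05 in 5 of 19), Mir379, Sdf2l1, Mir344-2 and Olfr329-ps (limma adjusted p of 0.571 to 0.665). Genes with both SMA libraries above both WT libraries in each region, or below them in each, made up 6.85% of those tested, where chance gives 5.56%. The genes followed throughout ranged from Smn1 at -2.88 to C1qb at 1.27, the latter with limma adjusted p = 0.604. The count was 8 without SMA motor neuron replicate 1, 5 without SMA motor neuron replicate 2 and 1 without WT white matter replicate 2.

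By camera, 10 lists passed over both regions, 8 rising and 2 falling, and none held with an estimated correlation. The median over all genes was 0.11 on the deposited scale and -0.0099 with median-of-ratios scaling. These calls were not repeated under other scaling or with single libraries left out. Here too, the complement list was not tested without its C1q genes. The p53 target list had 25 of 27 positive with a median of 0.46 (camera adjusted p = 6.2e-07; adjusted p = 0.401 with an estimated correlation). In it 6 members passed adjusted over the list alone, against 0 over all genes: Cdkn1a, Sesn2, Plk2, Gtse1, Psrc1 and Dcxr. Fibroblast or meninges genes (16 of 16 positive, median 0.63), endothelium genes (21 of 22, 0.45), pericyte genes (11 of 13, 0.49) and astrocyte genes (21 of 24, 0.24) rose (highest camera adjusted p = 0.00151; adjusted p = 0.479 with an estimated correlation for each). Microglia genes (21 of 24 positive, median 0.29; camera adjusted p = 0.00451) and complement genes (15 of 19, 0.27; 0.0314) rose with adjusted p = 0.458 with an estimated correlation. Spinal interneuron genes (14 of 15, 0.29; camera adjusted p = 0.0331) rose with adjusted p = 0.598 with an estimated correlation. Histone genes (median -0.12; camera adjusted p = 1.2e-05; adjusted p = 0.860 with an estimated correlation) and cholesterol synthesis genes (-0.13; 5.2e-04; adjusted p = 0.598 with an estimated correlation) fell. Median or mean lay above 0 while the camera direction was down for the motor neuron, proliferating cell, SMN complex, unfolded protein response, interferon response, channel, receptor and ribosomal protein lists, none of them called.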

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

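The tests of the p53 target, C1q and meninges patterns in this part were chosen only after the results were seen, as was the choice to test the lists for a difference between regions; the counts over other splits of the libraries were planned. Between motor neurons and white matter the SMA against WT change differed for 6 lists by camera on the interaction, where the median of all genes was -0.33. None of the 6 held with an estimated correlation (adjusted p = 0.675 to 0.889 with an estimated correlation). The motor neuron list had a median interaction of -0.77 (camera adjusted p = 0.0102), with medians of -0.38 in motor neurons and 0.34 in white matter and 22 of 26 genes negative. The spinal interneuron list was at 0.14 (0.00642; 0.43 and 0.29), the histone list at 0.21 (1.9e-07; 0.016 and -0.19) and the p53 target list at 0.25 (7.8e-05; 0.59 and 0.40). The cholesterol synthesis list was at 0.12 (0.00713; -0.13 and -0.22) and the respiratory chain list at -0.34 (0.0394; -0.031 and 0.33). The p53 call held without any single library, though its median against all genes fell from 0.58 to 0.35 without WT white matter replicate 2.

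Other calls on the interaction were lost when 1 library was left out. The motor neuron call was lost without SMA motor neuron replicate 1 (camera adjusted p = 0.394), WT white matter replicate 2 (0.158) or SMA white matter replicate 1 (0.157), and the interneuron call without SMA motor neuron replicate 2 (0.290) or WT white matter replicate 1 (0.288). The histone call was lost without SMA motor neuron replicate 2 (0.154) or WT white matter replicate 1 (0.546). The cholesterol call was lost without SMA motor neuron replicate 1 (0.188), WT white matter replicate 1 (0.293) or SMA white matter replicate 2 (0.0939). The respiratory chain call was lost without WT motor neuron replicates 1 (0.135) and 2 (0.0529), SMA motor neuron replicates 1 (0.156) and 2 (0.110), WT white matter replicate 2 (0.886) or SMA white matter replicate 1 (0.222), each left out alone. Other settings ended 3 of the calls. The interneuron call was lost with a pseudocount of 0.1 RPKM (camera adjusted p = 0.140), median-of-ratios scaling (0.0688), quantile normalization (0.0946) and voom (0.628). The respiratory chain call was lost with median-of-ratios scaling (0.848), quantile normalization (0.543) and voom (0.198), and the motor neuron call with voom (0.116).

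The p53 target genes were higher in SMA than in WT motor neurons with a median of 0.59 (quartiles 0.25 and 1.01). White matter RNA at its WT levels fell short of it. The share allowed by the upper quartile of the white matter genes, 14.1%, would give the list a median of 0.045. SMA white matter levels, with the list at a median change of 0.40 there, were not used. Scaling did not account for the rise in motor neurons either, since the median was 0.62 with median-of-ratios scaling. A response to SMA in the captured cells and differences between animals, which the labels do not name, were not tested and stay open. Other changes in the cell mix were not tested either. In the same captures the motor neuron list had a median of -0.38 and the spinal interneuron list 0.43.

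C1qa, C1qb and C1qc were higher in SMA than in WT motor neurons. For white matter RNA at its WT levels to bring these values, it would make up 26.6 to 36.8% of the SMA captures. At the smallest share, 1281 genes that mark white matter would have a median change of 0.61. The observed median of the 1281 genes was 0.096 (quartiles -0.14 and 0.36). SMA white matter levels, which were higher than WT for C1qb and C1qc, were not used. For microglial RNA in general, the 24 microglia genes would have a median of 1.081, against an observed 0.17 (quartiles -0.055 and 0.76). Of these genes 4 of 24 reached their predicted change, and the 14 at 1 RPKM or more in WT motor neurons had a median of 0.068 where 1.25 was predicted. That cut on WT levels left out Cd68 (21 and 47 reads in WT, 256 and 344 in SMA motor neurons). It also left out Tmem119 (250 and 90, 512 and 326) and Cx3cr1 (275 and 214, 530 and 661). In the whole list 16 genes were positive and 8 negative. The values thus argue against both of these changes in the cell mix, modelled from WT levels, as the whole source. A change within microglia or other cells was not tested and stays open, and C1q was known from published work on these samples.

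Fibroblast or meninges genes were higher in SMA than in WT white matter. Scaling alone did not account for it, as the median was 0.78 with median-of-ratios scaling. More meningeal tissue in the SMA white matter captures and a change in these cells with SMA cannot be told apart. That 16 of 16 list genes changed by more than the median of all genes (0.33 to 1.48) only restates the pattern, and no other value decided between them.

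Over both regions, 0 genes passed limma in the real split of the 8 libraries (836 at unadjusted p under 0.05; voom called 1), and the highest of the other splits gave 5. At unadjusted p under 0.05, 5 of the splits gave at least 836 genes, the real one included, and the highest other gave 1767. The 18 splits that part 2 and 2 libraries per region are too few for a share under 0.05, and a real count of 0 is reached by any split. The split by replicate number called Ddx3y, Eif2s3y, Kdm5d, Tsix and Xist, the sex-linked genes that part replicate 1 from replicate 2.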

How the results depend on the processing

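The alternatives with voom on recovered reads and without small RNA genes were chosen only after the results were seen. For each result below the cause of a change was not tested. The count for SMA against WT motor neurons was 0 by limma (609 at unadjusted p under 0.05; 0 by voom). With no filter it was 1 (Olfr329-ps), and leaving out 1 library gave 0 to 123 genes, 123 without SMA motor neuron replicate 1. Camera lists there went from 7 to 0 with an estimated correlation and to 3 to 8 when 1 library was left out (4 without WT motor neuron replicate 1, 4 without SMA replicate 1 and 3 without SMA replicate 2).

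The white matter count was 0 by limma (880 at unadjusted p under 0.05). It was 1 with a pseudocount of 5 RPKM, 1 after quantile normalization, 2 with array weights, 1 in only the 4 libraries compared and 1 by voom. Leaving out 1 library gave 0 to 1, with 1 without SMA motor neuron replicate 1 or 2. Camera lists went from 8 to 0 with an estimated correlation. For Ptgds the adjusted p lay between 2.3e-04 and 0.964 over the alternatives.

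The interaction count was 0 by limma (693 at unadjusted p under 0.05; 0 by voom) and 0 to 17 when 1 library was left out, 17 without SMA motor neuron replicate 1. Its camera lists went from 6 to 0 with an estimated correlation and to 3 to 8 with 1 library left out. Over both regions the count was 0 by limma (836 at unadjusted p under 0.05). It was 2 with a pseudocount of 0.1 RPKM, 1 with a pseudocount of 5 RPKM, 1 with a filter of at least 5 RPKM, 3 after quantile normalization, 2 with array weights, 1 by voom and 2 without small RNA genes. Leaving out 1 library gave 0 to 8, with 8 without SMA motor neuron replicate 1, 5 without SMA motor neuron replicate 2 and 1 without WT white matter replicate 2.

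Between WT regions the count of 3967 became 2015 to 5333 when 1 library was left out: 2015 and 2108 without WT motor neuron replicates 1 and 2, 2586 and 2118 without WT white matter replicates 1 and 2. Its camera lists went from 19 to 1 with an estimated correlation. Between SMA regions the count of 4295 became 2415 in only the 4 libraries compared and 2272 to 5539 with 1 library left out, 2272 and 2410 without SMA white matter replicates 1 and 2.

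Some small changes turned direction. With a pseudocount of 0.1 RPKM, Isl1 (0.40) and Xist (-0.16) did so in the interaction and Chat (0.057) over both regions. With median-of-ratios scaling, Mnx1 did in motor neurons (0.033), and in white matter Agrn (-0.15), Gfap (-0.014) and Xist (-0.050). After quantile normalization they were Mnx1 in motor neurons (0.047), and in white matter Agrn (-0.18), Mnx1 (0.0020), Gfap (-0.077), Xist (-0.10) and the respiratory chain list (-0.028 against all genes). Quantile normalization also turned Agrn between WT regions (-0.22) and Mnx1 over both regions (0.025). By voom they were Xist in motor neurons (-1.74), Chat in white matter (-0.65), Xist over both regions (-0.54), and in the interaction Chat (0.13), Isl1 (0.93), Xist (-2.38), Lhx5 (-0.12) and Calb2 (-0.55).

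Leaving out 1 library moved some log2 changes across 0. In motor neurons the ranges were -0.17 to 0.15 for Mnx1, -0.14 to 1.40 for Igf2 and -1.90 to 2.34 for Xist. In white matter they were -0.054 to 0.031 for C1qa, -0.16 to 0.77 for Chat, -0.45 to 0.0060 for Isl1, -0.16 to 1.06 for Mbp, -0.089 to 0.010 for Mnx1 and -2.44 to 2.73 for Xist. In the interaction they were -0.45 to 0.0051 for Isl1, -0.13 to 0.19 for Mnx1 and -2.50 to 2.66 for Xist. Over both regions they were -0.12 to 0.016 for Agrn, -0.31 to 0.15 for Chat, -0.11 to 0.058 for Mnx1 and -1.11 to 1.47 for Xist, and between WT regions -3.10 to 1.85 for Xist.

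Medians of called lists, set against all genes, also moved by over 1.5 times or across 0 when 1 library was left out. In SMA motor neurons, apart from microglia (-0.016 to 0.34) and complement (0.11 to 0.36), the motor neuron list went from -0.33 to -0.12 without SMA replicate 1 and -0.21 without WT replicate 1, interneuron from 0.48 to 0.20 without SMA replicate 2, and astrocyte from 0.15 to 0.31 without SMA replicate 1. In white matter the respiratory chain list went from 0.060 to 0.19 without WT replicate 1, -0.094 without WT replicate 2 and 0.096 without SMA replicate 2. The synaptic vesicle list went from 0.17 to 0.27 and 0.033 without WT replicates 1 and 2 and 0.081 without SMA replicate 1, and astrocyte from 0.13 to 0.19 without WT replicate 2 and 0.010 and 0.20 without SMA replicates 1 and 2. The histone list went from -0.47 to -0.098 and -0.84 without WT replicates 1 and 2 and -0.70 and -0.28 without SMA replicates 1 and 2, and pericyte from 0.55 to 0.29 without SMA replicate 1.

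In the interaction the respiratory chain list lay at -0.0021 against all genes, and at -0.17 to 0.12 with 1 library left out. The motor neuron list went from -0.44 to -0.66 without SMA motor neuron replicate 2, -0.28 without WT white matter replicate 2 and -0.18 without SMA white matter replicate 1. The interneuron list went from 0.47 to 0.049 and 0.93 without WT white matter replicates 1 and 2 and 0.26 without SMA white matter replicate 1. The histone list went from 0.54 to 0.82 and 0.20 without SMA motor neuron replicates 1 and 2, 0.13 and 0.91 without WT white matter replicates 1 and 2 and 0.30 without SMA white matter replicate 2. The cholesterol list went from 0.45 to 0.26 without WT motor neuron replicate 1.

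Some genes that did not pass limma did so under alternatives. Between WT regions Etv1 passed with array weights (limma adjusted p = 0.0301), in only the 4 libraries compared (0.0430) and without SMA motor neuron replicates 1 (0.0405) or 2 (0.0402). Over both regions Cdkn1a passed under 10 of 19 alternatives. Smn1 passed under 5, with a pseudocount of 0.1 RPKM (limma adjusted p = 0.0272), after quantile normalization (0.0476), without SMA motor neuron replicates 1 (0.0334) or 2 (0.0488) and without small RNA genes (0.0427). Ptgds passed under 4 (lowest limma adjusted p = 7.7e-04, without SMA motor neuron replicate 2). Without SMA motor neuron replicate 1, replicate 2 alone stood for that group. Cdkn1a, C1qb, Mir379 and Slit2 then passed in motor neurons, Mir453 in the interaction, and Mt2 and Ccl3 over both regions. Igf2 passed over both regions without SMA motor neuron replicate 2 (limma adjusted p = 0.0488), and Mir453 in white matter with array weights (0.0386).

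With the replicate number as a replicate block, the counts were 0 in motor neurons (620 at unadjusted p under 0.05), 0 in white matter (953), 0 in the interaction (703), 0 over both regions (887), 3848 between WT regions and 4138 between SMA regions, all by limma. Pairing within genotype gave 3868 and 4211 between regions. After group means were removed, libraries of the same number correlated at -0.0025 to 0.069. Sex-linked genes still followed the number, with Xist higher in replicate 1 and Ddx3y in replicate 2 of each group, so whether libraries of the same number were paired stays open.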

Other observations

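The genes in this part were chosen only after their values were seen, and the microRNA test was too. Genes of the Dlk1-Dio3 region were those placed between Dlk1 and Dio3 in the reference annotation of another build. The microRNA genes of the Dlk1-Dio3 region had a median log2 change of -0.62 in SMA motor neurons, with 33 of 48 lower (camera against all other genes, p = 2.9e-06; 0.0474 with an estimated correlation). For 201 other microRNA genes it was -0.17, a contrast that camera did not test. The median of the region was -1.06 in SMA replicate 1 and -0.26 in replicate 2. In white matter the region was at -0.15, with 29 of 48 lower (camera against all other genes, p = 3.8e-11; 0.0162 with an estimated correlation). There the median was 0.044 for the other microRNA genes and 0.27 for all genes. The host transcripts Meg3, Rian and Mirg were at -0.0099, -0.62 and -0.33 in motor neurons and at -0.19, -0.12 and -1.12 in white matter.

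Single libraries stood apart for some genes. Fabp7, a radial glia gene, was at 935 and 486 RPKM in the WT motor neuron libraries and at 1431 and 129 in the SMA ones. Slit2 had 31045 and 27525 reads in the WT motor neuron libraries and 24656 and 7839 in the SMA ones. The glycolysis gene Pgk1 had 3230 and 2736 reads in WT and 3955 and 194 in SMA motor neurons. Ccl3 had 355 reads in SMA motor neuron replicate 2 and 0 in the other motor neuron libraries. The skeletal muscle genes Acta1 and Mylpf were at 148 and 121 RPKM in SMA white matter replicate 2. There the red blood cell list lay 1.73 above the WT mean, against 0.11 in replicate 1. Ddx3y, on the Y chromosome, was listed at 0 in replicate 1 of each group and at 3.65, 0.628, 5.73 and 6.37 RPKM in replicate 2 of WT motor neurons, SMA motor neurons, WT white matter and SMA white matter.

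Gapdh, a glycolytic gene often used as a reference, lay at 1.21 to 6.34 RPKM, and Hmgcs1 was listed at 0 in all 8 libraries. The chemokine gene Ccl3 was at 5.48 and 8.49 RPKM in SMA white matter and at 0.888 and 0.969 in WT white matter. Timp1, an inhibitor of matrix proteases, was at 10.2 and 9.35 RPKM there and at 2.02 and 3.58 in WT.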
